A study of Mus musculus with 9 samples.

How the data were processed

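RNA was measured in 9 libraries of bone marrow-derived macrophages (BMDMs), primary mouse cells grown from bone marrow, after 24 h with DMSO, with 1 µg/mL imiquimod or with lipopolysaccharide (LPS). Each of the 3 groups held 3 libraries. Per the labels' protocols, mRNA was selected on oligo(dT) beads, fragmented, copied into cDNA from random primers, amplified by PCR and sequenced as read pairs of 150 bases per read. The labels do not give the LPS dose, and they do not state that the library kit marked strand.

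The deposited table holds estimated counts per gene, as RSEM gives them, which are not normalized and need not be whole. Per the submitters' processing notes, the tools were fastp, HISAT2, StringTie, RSEM and DESeq2 and the genome build was GRCm39. Their versions, order and settings, the annotation release and the strand setting of the counting are not given in the sources used here. Estimated counts were rounded to whole numbers before every test, so a read that RSEM divided among several genes enters each of them in part. The table has 55664 entries, 52081 of them with a gene symbol and 250 of them transcripts assembled by StringTie without a reference identifier. Genes are named by the symbols that a separate reference of gene names pairs with the table's Ensembl identifiers. Entries without a symbol hold 0.255% to 0.356% of the counts of a library and were kept in library sizes and tests. A reference annotation of an earlier build, GRCm38, was used for exon lengths, coding lengths, exon overlaps between genes and searches for near-identical copies, and no coordinates are given because the builds differ.

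Library totals ran from 20536538 to 29748678 counts, with 18694 to 19608 genes above 0. Counts were scaled by TMM (trimmed mean of M values), whose factors lay between 0.9761 and 1.036. Genes with low counts were removed with filterByExpr, which left 13513 genes. The quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 was fitted to all 9 libraries together with the group as the only term and robust estimation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The common dispersion was 0.0039, a biological coefficient of variation of 6.2%. Fold changes are log2 values with a prior count of 0.125. The standard error printed with each is its absolute value divided by the square root of the test's F, and so is approximate. Expression levels are in CPM, counts relative to the TMM-scaled library total, as mean and SD of 3 libraries. Ratios that rest on fewer than 6 counts in a group are given with an exact binomial 95% interval of the summed counts, which covers counting error only, since PCR copies without molecular identifiers are not independent molecules.

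Gene lists, 34 in all, were written before the data were examined, as were the groups, the tests, the alternatives and the rule for naming genes. They cover cytokines, chemokines, activation states, signalling, metabolism, stress, cell division, ribosomal and mitochondrially encoded genes, and markers of other cells that a bone marrow culture could hold. Of their 774 members, 700 were tested, 4 of them found under an older symbol. Lists with at least 5 tested members, 33 of them, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. A list's members are counted as called over all genes tested and also adjusted over the list alone. The lists shortened below to NRF2 targets and LXR targets are, in full, NRF2 targets and oxidative stress, and LXR targets and lipid efflux.

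Named genes were chosen by rule. A panel of 20 genes is named whatever the result. In each comparison, the 6 largest increases and 6 largest decreases are named among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups. Clone and prediction names were left out. Of each list described, at most 2 called members that rose most and 2 that fell most are named. Any other gene is said to be chosen after its values were seen.

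The procedure was tested on simulated data with 200 genes changed in each comparison, drawn from the means and library sizes of the real libraries. For imiquimod against DMSO (13336 genes), 72.73% of 1.5-fold, 87.69% of 2-fold and 98.46% of 4-fold changes were recovered, and 7.14% of the calls were unchanged genes. For LPS against DMSO (13339 genes) the shares were 82.09%, 86.15%, 98.46% and 9.33%. For imiquimod against LPS (13326 genes) they were 72.31%, 87.88%, 96.97% and 5.59%.

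Counts of libraries of the same group differed by more than sampling noise in every pair, with a chi-square per degree of freedom between 2.15 and 21.8. The pairs lay at 2.15 to 3.43 with DMSO, 3.56 to 4.07 with LPS and 5.1 to 21.8 with imiquimod. The fit shared its estimate of spread across groups, so it can understate the spread with imiquimod. The chi-square covers counting error only. Repeat libraries of the same RNA sample would also pass that test, so it does not show that the samples are separate. The alternatives tried were other scalings, the Wald test of DESeq2 1.42.0, voom of limma with quality weights, other filters on low counts, a fold minimum of 1.5, fits to the compared groups alone, fits with the replicate number of the labels as a block, each library left out in turn, an estimated correlation in camera, and fry. The labels call the samples of a group independent but do not say that they came from separate animals or cultures. The p-values of the gene tests therefore measure the spread between these samples, which may be technical. Camera with the preset correlation sets a list's genes against all other genes tested. Its p-values rest on the spread across genes, so very small ones do not measure the spread between samples. Genes with near-identical copies or relatives, such as those of the Gbp, Apol9, Fpr and H2-Q families and the mitochondrially encoded genes, are uncertain, because the counting could divide their reads. Without a stated strand setting, the same holds for genes that overlap another gene, among them Il1b, Cxcl10, Irak3, Cd180, Lrrc14b, Fpr2 and Ciita.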

Results

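Macrophages grown from mouse bone marrow were treated for 24 h with DMSO, the solvent and negative control, with imiquimod, an imidazoquinoline that activates Toll-like receptor 7 (TLR7), or with LPS, a component of bacterial outer membranes that activates TLR4 and served as the positive control. Poly(A)-selected RNA from 3 libraries per group was sequenced, and the libraries held between 20536538 and 29748678 counts. Pearson correlations of log expression across genes were 0.9886 to 0.9922 within groups and 0.9712 to 0.9844 between groups. The first principal component held 46% of the variance and the second 22.2%. The third, with 7.32%, set imiquimod libraries 2 and 3 apart.

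The panel of macrophage activation genes gave the levels against which the comparisons can be read. Tnf (ENSMUSG00000024401), the gene of the cytokine TNF, stood at 33.3 ± 3.36 CPM (TMM-scaled counts relative to the library total; mean ± SD, n = 3 here and below) with DMSO, 124 ± 7.03 with imiquimod and 162 ± 5.51 with LPS. For Cxcl10, a chemokine gene induced by interferons, the means were 4.7 ± 0.433, 11.3 ± 1.26 and 163 ± 8.67 CPM. Mrc1, which encodes the mannose receptor, stood at 139 ± 9.1, 30.6 ± 2.28 and 32.3 ± 0.951 CPM. Ptgs2, which encodes cyclooxygenase-2, stood at 2.09 ± 0.114, 6.61 ± 1.01 and 7.84 ± 0.587 CPM. Il12b, another panel gene, had at most 8 counts in any library and was not tested.

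**Figure D1:**
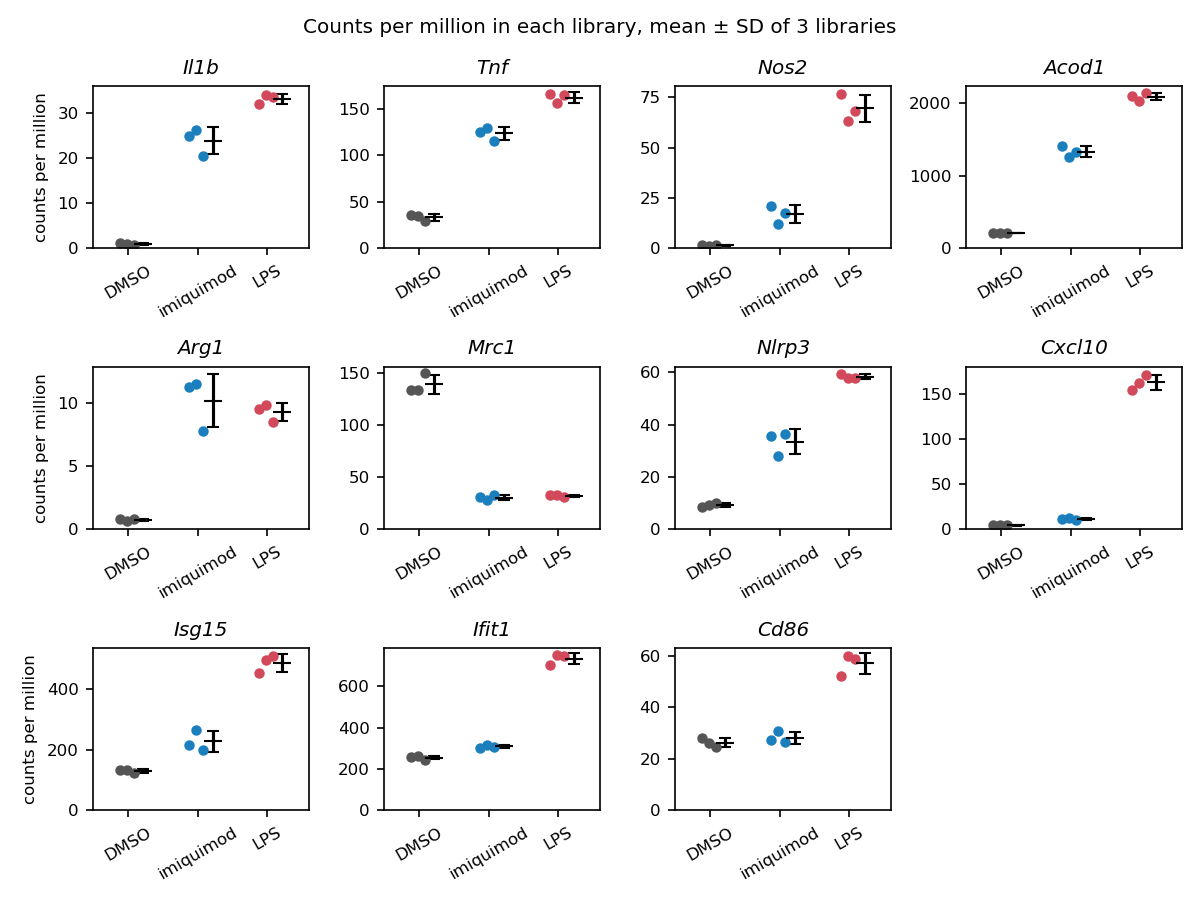
Expression in CPM of 11 panel genes in each library, with dots for single libraries and bars for the mean ± SD of the 3 libraries of a group; the vertical axes start at 0 and differ between genes. Cxcl10, Isg15, Ifit1 and Cd86 were higher in every LPS library than in any imiquimod library, whereas the Mrc1 means with imiquimod and LPS were 30.6 and 32.3.

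The first comparison, imiquimod against DMSO, addressed what the compound under study changed in macrophages. Imiquimod raised transcripts of inflammatory mediators. Il1b, the gene of interleukin-1β, rose from 0.989 ± 0.174 to 23.9 ± 2.98 CPM (log2 fold change 4.59 ± 0.14, adjusted p = 7.07e-13), and Acod1, whose enzyme makes itaconate, rose from 212 ± 0.954 to 1330 ± 79.1 CPM (2.65 ± 0.05, adjusted p = 3.62e-15). Mrc1 fell by 2.19 on the log2 scale (SE 0.07, adjusted p = 7.39e-13). Genes of mitosis fell as a group, with a median log2 fold change of -0.60, and the median of the interferon-stimulated genes was 0.12.

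In all, 4496 of 13513 genes (33.3%) were called, 2390 higher and 2106 lower with imiquimod. At least 2-fold changes were found in 385 of the higher and 381 of the lower genes. The libraries of both groups did not overlap for 43.8% of the genes, where chance gives 10%. Among the largest increases were Cd300e, an activating receptor of myeloid cells (log2 fold change 5.42 ± 0.12), Zfp811, a zinc finger gene (5.10 ± 0.24), the neutrophil-attracting chemokine gene Cxcl3 (4.68 ± 0.16), Socs3, a feedback inhibitor of cytokine signalling (4.39 ± 0.08), and Gpr84, a receptor for medium-chain fatty acids (4.35 ± 0.07). Their adjusted p-values ran from 8.72e-16 for Gpr84 to 9.72e-11 for Zfp811. The largest decreases were those of Lrrc14b (-4.95 ± 0.09), Fam198b (-3.27 ± 0.15), Pcp4l1 (-3.26 ± 0.18), the costimulatory receptor gene Cd28 (-2.98 ± 0.12) and the T-cell receptor segments Trav13-4-dv7 (-2.74 ± 0.09) and Trav13n-4 (-2.62 ± 0.22). Lrrc14b overlaps Ccdc127 (-0.73 ± 0.05), named for that overlap after its values were seen, and without a stated strand their reads could not be told apart.

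Of the 33 lists tested, 16 were called, 11 higher and 5 lower. The classical activation markers showed the lowest adjusted p: 20 of 24 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 5.08e-94), with a median of 1.84. Besides Socs3 they included Gpr18 (3.99 ± 0.22) and the panel genes Nos2, which encodes inducible nitric oxide synthase (3.56 ± 0.24, adjusted p = 8.88e-07), and Cd40 (1.78 ± 0.12). Cd86, a costimulatory ligand, had a log2 fold change of 0.10 ± 0.08 (adjusted p = 0.369). NF-kB pathway genes and their feedback inhibitors rose in 21 of 27 cases and fell in 1 (21 and 1 adjusted over the list alone; adjusted p = 6.3e-28), led by Sod2, the mitochondrial superoxide dismutase (2.69 ± 0.06), and Nfkbiz (2.22 ± 0.08). Pro-inflammatory cytokine genes rose in 12 of 18 cases and fell in 3 (12 and 4 adjusted over the list alone; adjusted p = 1.46e-08). Csf3, the gene of granulocyte colony-stimulating factor, had 4 counts in the DMSO libraries together and 181 with imiquimod, a ratio of 43.4 (95% interval 16.7 to 161). For Il6 the sums were 3 and 43 counts, a ratio of 13.7 (4.4 to 69.3). Csf1, the gene of the growth factor that sustains macrophages, fell by 1.33 on the log2 scale (SE 0.06), and Il18 by 0.66 (SE 0.12).

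Mitosis genes fell in 20 of 28 cases and rose in 0 (23 and 0 adjusted over the list alone; adjusted p = 6.18e-06), among them Cenpa of the centromere (-1.37 ± 0.11) and Kif23, a motor of cytokinesis (-1.27 ± 0.12). The alternative activation markers fell in 7 of 14 cases and rose in 2 (8 and 3 adjusted over the list alone; adjusted p = 4.74e-05). Pparg, a lipid-sensing nuclear receptor, fell by 2.48 on the log2 scale (SE 0.14) and Clec10a by 2.58 (SE 0.33), while Arg1, the arginase gene, rose from 0.746 ± 0.0736 to 10.2 ± 2.1 CPM (3.75 ± 0.19, adjusted p = 3.67e-10). With an estimated correlation, these 5 lists kept their calls: pro-inflammatory cytokines (adjusted p = 0.0237), NF-kB (0.00376), classical activation (0.00192), alternative activation (0.024) and mitosis (0.0237).

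The other 11 called lists lost their calls with an estimated correlation, and that adjusted p follows each. Chemokine genes rose in 9 of 18 cases and fell in 1 (10 and 2 adjusted over the list alone; adjusted p = 4.77e-06, and p = 0.247 with an estimated correlation). Cxcl1 had a log2 fold change of 3.67 ± 0.25 and Ccl6 one of -1.13 ± 0.08. Interferon-stimulated genes rose in 21 of 45 cases and fell in 7 (21 and 9 adjusted over the list alone; adjusted p = 0.000247, and p = 0.253 with an estimated correlation). The guanylate-binding protein genes Gbp2 (1.39 ± 0.05) and Gbp5 (1.30 ± 0.07) rose most, Isg15 rose by 0.81 ± 0.09 and Ifit1 by 0.28 ± 0.05, and the antiviral gene Oas2 fell by 0.25 on the log2 scale (SE 0.06). MHC class I genes rose in 14 of 22 cases and fell in 0 (14 and 0 adjusted over the list alone; adjusted p = 6.27e-06, and p = 0.345 with an estimated correlation). H2-Q6 had a log2 fold change of 1.38 ± 0.06. Anti-inflammatory mediators rose in 9 of 19 cases and fell in 6 (the same counts adjusted over the list alone; adjusted p = 0.000251, and p = 0.0963 with an estimated correlation). Il10 rose by 1.50 ± 0.16 and Fpr2, a formyl peptide receptor gene, by 3.47 ± 0.10, whereas the inhibitory receptor gene Cd200r1 fell by 0.79 (SE 0.05). Immediate-early and heat-shock genes rose in 11 of 17 cases and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.0101, and p = 0.0998 with an estimated correlation). Ier3 had a log2 fold change of 1.99 ± 0.08 and Jun one of -0.74 ± 0.05.

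Metabolic and stress lists also moved. Glycolysis genes rose in 16 of 20 cases and fell in 2 (the same adjusted over the list alone; adjusted p = 1.48e-11, and p = 0.0998 with an estimated correlation), among them the lactate exporter Slc16a3 (1.23 ± 0.07) and the phosphofructokinase gene Pfkl (1.17 ± 0.05). NRF2 targets rose in 17 of 26 cases and fell in 3 (the same adjusted over the list alone; adjusted p = 4.78e-09, and p = 0.16 with an estimated correlation). That list also holds oxidative stress genes, and Sod2, named above for NF-kB, rose most in it. The peroxiredoxin gene Prdx5 had a log2 fold change of 1.71 ± 0.07. For the integrated stress response, 14 of 25 rose and 2 fell (16 and 3 adjusted over the list alone; adjusted p = 0.00633, and p = 0.179 with an estimated correlation). The cystine transporter Slc7a11 had a log2 fold change of 1.52 ± 0.09 and Atf3 one of -0.90 ± 0.05. Lysosome and autophagy genes fell in 21 of 34 cases and rose in 5 (24 and 5 adjusted over the list alone; adjusted p = 6.18e-06, and p = 0.179 with an estimated correlation). Atp6v0d2, a subunit of the proton pump, fell from 296 ± 8.76 to 65.3 ± 1.96 CPM, and Lipa, the lysosomal acid lipase, from 1200 ± 1.43 to 618 ± 25.4 CPM. LXR targets fell in 9 of 18 cases and rose in 6 (the same adjusted over the list alone; adjusted p = 0.00688, and p = 0.0998 with an estimated correlation), with lipoprotein lipase, Lpl, at -1.58 ± 0.06 and Scd2 at 1.17 ± 0.08. Osteoclast markers fell in 4 of 7 cases and rose in 2 (the same adjusted over the list alone; adjusted p = 0.0032, and p = 0.0879 with an estimated correlation). That list lost its call without a low-count filter (adjusted p = 0.0773), and Atp6v0d2 is also one of its members.

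The remaining lists were not called with imiquimod, although single members were. Toll-like receptors and adaptors had 8 of 25 genes higher and 7 lower (the same adjusted over the list alone; camera adjusted p = 0.117), with a median of -0.03, a mean of 0.18 and an upward test direction. Cd14, the LPS co-receptor, rose by 2.10 ± 0.06, Cd180 fell by 1.19 (SE 0.06), and Tlr7 and Tlr4 each fell by 0.36 (SE 0.07). Csf1r, the receptor for the product of Csf1, was not called (0.10 ± 0.05, adjusted p = 0.168). Inflammasome genes had 7 of 20 higher and 6 lower (adjusted p = 0.586). Nlrp3 had a log2 fold change of 1.86 ± 0.10. MHC class II genes had 1 of 14 higher and 6 lower (adjusted p = 0.389), phagocytic, scavenger and complement receptors 9 of 33 higher and 17 lower (adjusted p = 0.697), and homeostatic macrophage identity genes 6 of 24 higher and 11 lower (adjusted p = 0.713). Marco, a scavenger receptor, rose from 57.7 ± 1.56 to 412 ± 30.3 CPM, and Gas6, a bridging ligand for apoptotic cells, fell from 262 ± 3.3 to 83.4 ± 3.38 CPM. Respiratory complex I (11 of 36 higher, 0 lower, adjusted p = 0.158) and the tricarboxylic acid cycle (4 of 22 higher, 3 lower, adjusted p = 0.697) were likewise not called. Neither were cholesterol synthesis (1 of 23 higher, 8 lower, adjusted p = 0.263), the unfolded protein response (5 of 20 higher, 5 lower, adjusted p = 0.661) and DNA replication (2 of 28 higher, 6 lower, adjusted p = 0.345). The ribosomal proteins (6 of 34 higher, 0 lower, adjusted p = 0.231) were not called, and no member was called adjusted over the list alone. Mitochondrially encoded genes had 1 of 13 higher (adjusted p = 0.628), and their median of 0.11 and mean of -0.48 differed in sign because of mt-Co3, which had a log2 fold change of -7.66 ± 3.52 and was not called (adjusted p = 0.155). That gene was chosen after its values were seen, as was the addition of counts from near-identical nuclear copies, after which the mean was 0.16 and the 13 genes lay between 0.07 and 0.32.

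Markers of other cells were tested as well. Neutrophil and granulocyte precursor markers had 4 of 12 genes lower and 0 higher with imiquimod (adjusted p = 0.189), with the myeloperoxidase gene Mpo falling from 2.65 ± 0.0774 to 0.385 ± 0.166 CPM. Lymphocyte markers had 3 of 9 higher and 1 lower (adjusted p = 0.679). Ighm, the heavy chain of IgM, rose from 11 ± 0.475 to 20.7 ± 3.33 CPM. Neither the dendritic cell (1 of 5 higher, 1 lower, adjusted p = 0.8), mast cell and basophil (0 of 6 higher, 2 lower, adjusted p = 0.661) nor stromal lists (1 of 11 higher, 1 lower, adjusted p = 0.661) were called. Only 3 erythroid markers were tested, too few for a list test, with the transferrin receptor gene Tfrc at -0.69 ± 0.06 and Car2 at 1.21 ± 0.22.

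The second comparison, LPS against DMSO, measured the response of the positive control. LPS raised the interferon-stimulated genes as a whole, with 45 of 45 called higher and a median log2 fold change of 1.07. It raised inflammatory genes as well: Nos2 rose from 1.45 ± 0.194 to 69.6 ± 6.77 CPM (5.58 ± 0.22, adjusted p = 6.35e-09) and Il1b from 0.989 ± 0.174 to 33.3 ± 1.13 CPM (5.07 ± 0.13, adjusted p = 1.19e-13). MHC class II genes rose in 9 of 14 cases (adjusted p = 0.108 with an estimated correlation). Mitochondrially encoded genes fell in 8 of 13 cases, with a median of -0.91 (adjusted p = 0.0559 with an estimated correlation), and ribosomal protein genes in 26 of 34, with a median of -0.29 (adjusted p = 0.555 with an estimated correlation).

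LPS changed 4772 genes (35.3%), 2410 higher and 2362 lower, of which 630 and 274 changed at least 2-fold. With scaling by library size alone the split was 2132 higher and 2718 lower, so the share of higher calls moved from 50.5% to 44%. Libraries did not overlap for 51.2% of the genes, against 10% by chance. Cxcl11, an interferon-induced chemokine gene, had 5 counts in the DMSO libraries together and 391 with LPS, a ratio of 81.6 (95% interval 34.7 to 253). After it and Nos2 came Cxcl10 (5.12 ± 0.09, adjusted p = 9.31e-16), Il1b, the interleukin-23 receptor gene Il23r (5.06 ± 0.21) and Rasgrp1, an activator of Ras (4.94 ± 0.16). The largest decreases were those of Pcp4l1 (-3.27 ± 0.19), the sodium-proton exchanger Slc9a9 (-2.84 ± 0.08), the cell cycle inhibitor Cdkn1c (-2.81 ± 0.16), Cd28 (-2.55 ± 0.11), Zfyve28 (-2.46 ± 0.17) and the sialyltransferase St6gal1 (-2.45 ± 0.11).

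Of the 33 lists, 24 were called, 14 higher and 10 lower. Interferon-stimulated genes (camera adjusted p = 1.93e-92; 45 of 45 also adjusted over the list alone) included Gbp5 (3.29 ± 0.07), Slfn4 (3.01 ± 0.06), Isg15 (1.91 ± 0.09) and Ifit1 (1.53 ± 0.05). Classical activation markers rose in 22 of 24 cases and fell in 0 (23 and 0 adjusted over the list alone; adjusted p = 2.81e-90). Ptges, a prostaglandin E synthase, had a log2 fold change of 3.92 ± 0.06, Cd40 one of 2.93 ± 0.12 and Cd86 one of 1.12 ± 0.08. NF-kB genes rose in 22 of 27 cases and fell in 0 (the same adjusted over the list alone; adjusted p = 6.72e-34). Nfkbie had a log2 fold change of 2.31 ± 0.06. Pro-inflammatory cytokine genes rose in 15 of 18 cases and fell in 2 (the same adjusted over the list alone; adjusted p = 1.96e-18). Tnf rose by 2.28 ± 0.07 and Il6 reached 20.2 times its DMSO level (95% interval 6.57 to 101, from 58 against 3 counts), while Csf1 fell by 0.24 (SE 0.06) on the log2 scale. Anti-inflammatory mediators rose in 11 of 19 cases and fell in 5 (12 and 6 adjusted over the list alone; adjusted p = 2.2e-07). Socs3 had a log2 fold change of 3.88 ± 0.08 and Il10 one of 1.57 ± 0.16. These 5 lists kept their calls with an estimated correlation, at adjusted p = 0.00154, 0.00154, 0.00282, 0.00358 and 0.0283 in this order.

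Chemokine genes rose in 14 of 18 cases and fell in 1 (15 and 1 adjusted over the list alone; adjusted p = 9.39e-19, and p = 0.0559 with an estimated correlation), with Ccl5 rising from 789 ± 13.9 to 2300 ± 47.6 CPM. MHC class I genes rose in 20 of 22 cases and fell in 1 (20 and 2 adjusted over the list alone; adjusted p = 2.14e-23, and p = 0.0559 with an estimated correlation). H2-Q6 had a log2 fold change of 2.67 ± 0.06 and the chaperone Calr one of -0.27 ± 0.05. In the MHC class II list 9 of 14 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 4.75e-05, and p = 0.108 with an estimated correlation). The class II transactivator Ciita had a log2 fold change of 1.41 ± 0.15 and Cd83 one of -0.88 ± 0.09. Toll-like receptors and adaptors rose in 12 of 25 cases and fell in 6 (the same adjusted over the list alone; adjusted p = 0.00093, and p = 0.115 with an estimated correlation). Tlr2 had a log2 fold change of 1.90 ± 0.06 and Tlr4 one of -0.30 ± 0.07, while Tlr7 was not called (0.08 ± 0.07, adjusted p = 0.383). Inflammasome genes rose in 10 of 20 cases and fell in 5 (11 and 5 adjusted over the list alone; adjusted p = 0.00774, and p = 0.135 with an estimated correlation). Nlrp3 had a log2 fold change of 2.66 ± 0.10. Alternative activation markers fell in 8 of 14 cases and rose in 4 (the same adjusted over the list alone; adjusted p = 0.00306, and p = 0.0559 with an estimated correlation). Mrc1 had a log2 fold change of -2.11 ± 0.07 and Arg1 one of 3.63 ± 0.20.

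Mitochondrially encoded genes (8 of 13 lower, 9 adjusted over the list alone; adjusted p = 3.78e-08, and p = 0.0559 with an estimated correlation) included mt-Cytb, which fell from 642 ± 55.5 to 296 ± 13 CPM. Ribosomal protein genes (26 of 34 lower and 1 higher, 28 and 1 adjusted over the list alone; adjusted p = 0.000251, and p = 0.555 with an estimated correlation) included Rpl10a (-0.76 ± 0.08) and Rpl3 (-0.69 ± 0.06). Mitosis genes fell in 19 of 28 cases and rose in 1 (20 and 1 adjusted over the list alone; adjusted p = 0.000247, and p = 0.0561 with an estimated correlation). Cenpa had a log2 fold change of -1.28 ± 0.11. Glycolysis genes rose in 15 of 20 cases and fell in 0 (16 and 2 adjusted over the list alone; adjusted p = 7.49e-06, and p = 0.174 with an estimated correlation). The glucose transporter Slc2a1 had a log2 fold change of 1.16 ± 0.07. NRF2 targets (13 of 26 higher, 6 lower, 13 and 7 adjusted over the list alone; adjusted p = 0.0189, and p = 0.504 with an estimated correlation) and the integrated stress response (16 of 25 higher, 2 lower, 16 and 3 adjusted over the list alone; adjusted p = 0.00103, and p = 0.108 with an estimated correlation) were called higher. Nupr1, a stress-induced nuclear protein gene, rose by 1.89 ± 0.08.

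Lists of lipid, energy and degradation genes were called lower with LPS. Lysosome and autophagy genes fell in 17 of 34 cases and rose in 5 (19 and 6 adjusted over the list alone; adjusted p = 0.000854, and p = 0.228 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 23 cases and rose in 1 (12 and 2 adjusted over the list alone; adjusted p = 0.0112, and p = 0.0911 with an estimated correlation). Sqle, the squalene epoxidase gene, fell by 0.78 on the log2 scale (SE 0.08). LXR targets fell in 8 of 18 cases and rose in 4 (8 and 5 adjusted over the list alone; adjusted p = 0.0112, and p = 0.108 with an estimated correlation), and Lpl fell by 1.71 (SE 0.06). In the tricarboxylic acid cycle 9 of 22 genes fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.0284, and p = 0.403 with an estimated correlation). Idh1, a cytosolic isocitrate dehydrogenase gene kept on that list, fell by 0.77 (SE 0.05).

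Among the called lists with LPS, 3 lost their calls under other alternatives as well. The unfolded protein response fell in 11 of 20 cases and rose in 1 (the same adjusted over the list alone; adjusted p = 0.0396, and p = 0.115 with an estimated correlation). Its call was lost without LPS replicate 1 (adjusted p = 0.0537) or 2 (0.0548). Osteoclast markers fell in 4 of 7 cases and rose in 2 (the same adjusted over the list alone; adjusted p = 0.0266, and p = 0.108 with an estimated correlation), and that call was lost without a low-count filter (0.199). Immediate-early and heat-shock genes rose in 8 of 17 cases and fell in 2 (9 and 3 adjusted over the list alone; adjusted p = 0.0396, and p = 0.121 with an estimated correlation). Their call was lost without LPS replicate 2 (0.0536) and in a fit to the 2 compared groups alone (0.0625).

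The 9 other lists were not called with LPS. Phagocytic, scavenger and complement receptors had 12 of 33 genes higher and 15 lower (adjusted p = 0.835), with a median of -0.11, a mean of 0.05 and an upward test direction. Clec4e, a receptor for mycobacterial glycolipids, rose from 158 ± 2.7 to 1300 ± 69.1 CPM, and Gas6 fell by 1.84 on the log2 scale (SE 0.05). Homeostatic identity genes had 6 of 24 higher and 11 lower (adjusted p = 0.108), and Csf1r rose by 0.29 ± 0.05. Complex I (0 of 36 higher, 7 lower, adjusted p = 0.212), DNA replication (3 of 28 higher, 7 lower, adjusted p = 0.334), neutrophil (2 of 12 higher, 3 lower, adjusted p = 0.694), lymphocyte (1 of 9 higher, 1 lower, adjusted p = 0.922), mast cell (1 of 6 higher, 1 lower, adjusted p = 0.817) and stromal lists (1 of 11 higher, 1 lower, adjusted p = 0.867) were not called. Dendritic cell markers (1 of 5 higher, 1 lower, adjusted p = 0.867) had a median of 0.06, a mean of 0.36 and a downward test direction.

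The third comparison, imiquimod against LPS, set the treated groups against each other in the fit to all 9 libraries. All 45 tested interferon-stimulated genes were lower with imiquimod than with LPS, with a median log2 difference of -0.84. Cxcl10 was lower by 3.86 on the log2 scale, at 11.3 ± 1.26 against 163 ± 8.67 CPM (-3.86 ± 0.08, adjusted p = 3.26e-14). MHC class II genes were lower in 9 of 14 cases. Mitochondrially encoded genes were higher with imiquimod in 8 of 13 cases, with a median of 0.98 (adjusted p = 0.0199 with an estimated correlation). Ribosomal protein genes were higher in 32 of 34 cases, with a median of 0.43, but the list lost its call with an estimated correlation (adjusted p = 0.324). Mrc1 (-0.07 ± 0.07, adjusted p = 0.481), Arg1 (0.13 ± 0.13, adjusted p = 0.527) and Il10 (-0.08 ± 0.14, adjusted p = 0.732) did not pass the test of a difference.

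Between these groups 3660 genes (27.1%) were called, 1805 higher and 1855 lower with imiquimod, of which 86 and 300 differed at least 2-fold. With scaling by library size alone the split was 2357 higher and 1596 lower, so the share of higher calls moved from 49.3% to 59.6%. Libraries did not overlap for 39.3% of the genes, against 10% by chance. The largest differences toward LPS were those of Cxcl11 (6 against 391 counts, 70.9 times higher with LPS, 95% interval 32.3 to 194), Ifit1bl1 (-4.39 ± 0.09), Cxcl10, Tgtp1, an interferon-induced GTPase gene (-3.80 ± 0.15), Gbp11 (-2.97 ± 0.19) and Apol9a (-2.97 ± 0.14). Toward imiquimod they were Zfp811 (2.03 ± 0.17), Rapgef5 (1.88 ± 0.11), Pald1 (1.64 ± 0.16), the dicarboxylate transporter Slc13a3 (1.62 ± 0.07), Marco (1.58 ± 0.06) and Cd300e (1.54 ± 0.08). Slc13a3 stood at 50.2 ± 3.68 CPM with DMSO, 209 ± 18.8 with imiquimod and 68.1 ± 3.56 with LPS.

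Of the 33 lists, 18 were called, 8 higher and 10 lower with imiquimod. The interferon-stimulated genes (45 of 45 lower, also adjusted over the list alone; adjusted p = 4.69e-150) kept their call with an estimated correlation (0.000678). So did MHC class II genes (9 of 14 lower and 0 higher, 12 and 1 adjusted over the list alone; adjusted p = 2.71e-14 and 0.0477). The same held for pro-inflammatory cytokines (12 of 18 lower and 0 higher, the same adjusted over the list alone; adjusted p = 7.25e-08 and 0.0477). Mitochondrially encoded genes kept theirs too (8 of 13 higher and 0 lower, the same adjusted over the list alone; adjusted p = 2.7e-20 and 0.0199). Iigp1 (-2.39 ± 0.08) and Isg20 (-2.19 ± 0.08) differed most among the first, Ciita (-1.86 ± 0.15) and H2-Eb1 (-1.66 ± 0.08) among the class II genes, and Tnfsf10, the gene of the death ligand TRAIL (-2.08 ± 0.16), and Il1f9 (-2.03 ± 0.17) among the cytokines. Of the panel, Tnf (-0.39 ± 0.06), Il1b (-0.48 ± 0.09), Nos2 (-2.03 ± 0.15), Cd86 (-1.02 ± 0.08) and Nlrp3 (-0.80 ± 0.08) were lower with imiquimod, and Il6 was not called (58 counts with LPS against 43, adjusted p = 0.385). Lower with imiquimod were also Acod1 (-0.65 ± 0.05), Ccl5 (-0.77 ± 0.07), Ifit1 (-1.24 ± 0.05), Isg15 (-1.10 ± 0.09) and Cd40 (-1.15 ± 0.10). Ptgs2 (-0.24 ± 0.12, adjusted p = 0.162) and Tlr4 (-0.06 ± 0.07, adjusted p = 0.558) were not called. Csf1r was called lower (-0.19 ± 0.05, adjusted p = 0.0118), a call lost without LPS replicate 1 (log2 difference -0.17).

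Other immune lists were also called lower with imiquimod than with LPS. MHC class I genes were lower in 19 of 22 cases and higher in 2 (20 and 2 adjusted over the list alone; adjusted p = 1.59e-18, and p = 0.157 with an estimated correlation). Chemokine genes were lower in 11 of 18 cases and higher in 1 (12 and 1 adjusted over the list alone; adjusted p = 3.6e-12, and p = 0.163 with an estimated correlation), the exception being Cxcl1 (1.31 ± 0.19). NF-kB genes were lower in 11 of 27 cases and higher in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.00195, and p = 0.206 with an estimated correlation), and Nfkbiz was among the higher ones (0.66 ± 0.07). Inflammasome genes were lower in 10 of 20 cases and higher in 1 (11 and 2 adjusted over the list alone; adjusted p = 0.00259, and p = 0.206 with an estimated correlation). Toll-like receptors and adaptors were lower in 13 of 25 cases and higher in 6 (14 and 6 adjusted over the list alone; adjusted p = 0.0173, and p = 0.298 with an estimated correlation). Tlr3, a receptor for double-stranded RNA, was lower with imiquimod (-0.89 ± 0.06), as was Tlr7 (-0.44 ± 0.07), while Cd14 was higher (0.46 ± 0.06). Anti-inflammatory mediators were lower in 7 of 19 cases and higher in 2 (8 and 3 adjusted over the list alone; adjusted p = 0.0173, and p = 0.234 with an estimated correlation), Socs3 being higher (0.51 ± 0.06). Classical activation markers were lower in 13 of 24 cases and higher in 5 (the same adjusted over the list alone; adjusted p = 0.0391, and p = 0.546 with an estimated correlation). Their call was lost without imiquimod replicate 3 (adjusted p = 0.434), without LPS replicate 3 (0.0683) and with scaling by library size alone (0.054).

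Besides the mitochondrially encoded genes, 7 lists were called higher with imiquimod than with LPS. Ribosomal protein genes were higher in 32 of 34 cases and lower in 0 (33 and 0 adjusted over the list alone; adjusted p = 3.03e-14, and p = 0.324 with an estimated correlation), among them Rpl3 (0.66 ± 0.06). NRF2 targets were higher in 16 of 26 cases and lower in 0 (19 and 1 adjusted over the list alone; adjusted p = 1.22e-05, and p = 0.298 with an estimated correlation), led by Gclm of glutathione synthesis (0.78 ± 0.06). Complex I genes were higher in 17 of 36 cases and lower in 0 (23 and 0 adjusted over the list alone; adjusted p = 4.19e-05, and p = 0.555 with an estimated correlation), including Ndufa12 (0.50 ± 0.08). In the tricarboxylic acid cycle 12 of 22 genes were higher and 0 lower (15 and 0 adjusted over the list alone; adjusted p = 0.000122, and p = 0.234 with an estimated correlation), with Idh3a at 0.64 ± 0.07. The unfolded protein response was higher in 9 of 20 cases and lower in 3 (9 and 4 adjusted over the list alone; adjusted p = 0.0272, and p = 0.174 with an estimated correlation), with the chaperone Hsp90b1 at 0.49 ± 0.05. Glycolysis genes were higher in 10 of 20 cases and lower in 1 (11 and 2 adjusted over the list alone; adjusted p = 0.0256, and p = 0.555 with an estimated correlation), a call lost without LPS replicate 3 (adjusted p = 0.0715). Cholesterol synthesis genes were higher in 7 of 23 cases and lower in 1 (the same adjusted over the list alone; adjusted p = 0.0448, and p = 0.206 with an estimated correlation). That call was lost without imiquimod replicate 2 (0.115) or 3 (0.0671), without LPS replicate 1 (0.0774) and with a filter of 1 CPM in 3 libraries (0.054).

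The 15 remaining lists were not called. Mitosis had 1 of 28 genes higher and 3 lower with imiquimod than with LPS (adjusted p = 0.661), alternative activation 1 of 14 and 3 (0.373), homeostatic identity 7 of 24 and 2 (0.0638), and phagocytic receptors 7 of 33 and 10 (0.423). For the lymphocyte (1 of 9 higher, median -0.03, mean 0.00), DNA replication (2 of 28 higher and 2 lower, 0.01 and -0.03) and immediate-early lists (6 of 17 higher and 5 lower, 0.04 and -0.07) the test pointed upward with adjusted p-values of 0.661, 0.974 and 0.67, and for osteoclast markers (1 of 7 higher and 2 lower, 0.03 and -0.08) it pointed downward with 0.463. The LXR (2 of 18 higher, 4 lower, adjusted p = 0.974), integrated stress (3 of 25 and 8, 0.331), lysosome (3 of 34 and 8, 0.335), neutrophil (0 of 12 and 2, 0.276), dendritic cell (1 of 5 and 0, 0.652), mast cell (0 of 6 and 1, 0.276) and stromal lists (1 of 11 and 1, 0.699) were not called either.

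**Figure D2:**
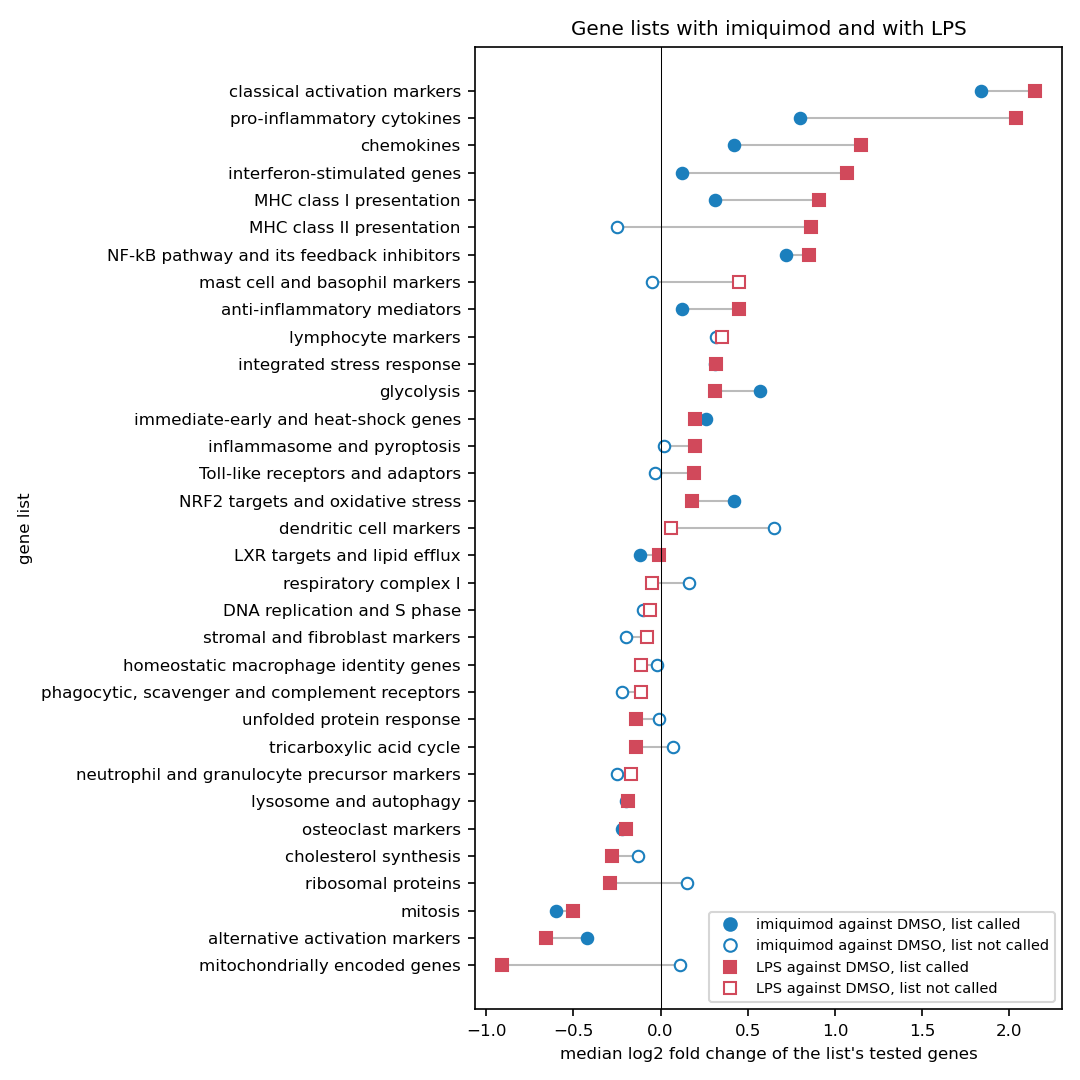
Median log2 fold change of the tested genes of each of 33 lists, for imiquimod against DMSO (blue circles) and LPS against DMSO (red squares), with filled symbols for lists that were called. Interferon-stimulated genes lie at 0.12 with imiquimod and 1.07 with LPS, and mitosis genes at -0.60 and -0.50.

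Both treatments were also compared gene by gene through their changes against DMSO. Of the called genes, 1352 were higher and 1385 lower with both, where independent lists would share 426.2 and 368.1. In 100 simulations of unchanged groups, all libraries were drawn from the DMSO means and both treated groups were tested against the same drawn DMSO libraries. At most 1 gene was called in the same direction, against 2737 observed. With no gene changed, this cannot measure what shared controls add to joint calls among changed genes. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.708, where the simulations gave a mean of 0.492 (0.382 to 0.655). With no gene changed, the simulated r comes from noise alone and is not a share of the observed r. The covariance was 0.256, against 0.0281 in the simulations (0.0215 to 0.0487), a difference of 0.228. Signs were the same for 70.6% of the genes, against 66.7%. The 3 DMSO libraries cannot be divided into parts of at least 2, so part of the shared calls and of r may come from the shared controls. On the covariance scale, what the simulations gave for shared controls, 0.0281, was small beside the observed 0.256. Among the 1352 genes higher with both, 589 also differed between imiquimod and LPS, 405 of them being higher with LPS. Among the 1385 lower with both, 378 differed, with 142 lower with LPS and 236 lower with imiquimod. Il1b, Tnf, Acod1 and Socs3 were among the genes higher with both, and Mrc1, Cd28 and Pparg among those lower with both.

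**Figure D3:**
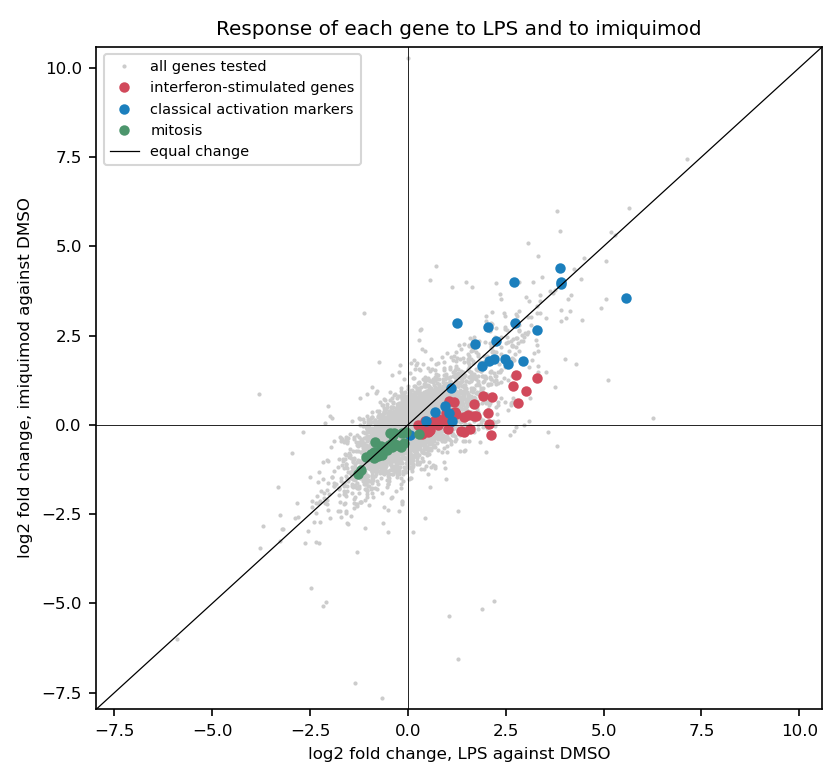
Log2 fold change against DMSO of each of 13513 genes with LPS (horizontal axis) and with imiquimod (vertical axis), with 3 lists in colour and the diagonal of equal change. The interferon-stimulated genes lie below the diagonal, with medians of 1.07 with LPS and 0.12 with imiquimod, and the mitosis genes lie near it.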

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

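Adding nuclear copies to mitochondrially encoded genes and matching on coding length were tests chosen after the results were seen.

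Some genes were called in opposite directions with the treatments, each against the same DMSO libraries. All of them were also called between imiquimod and LPS, which that selection all but fixes, so it adds no independent support. The genes called higher with imiquimod and lower with LPS numbered 49, and those called lower with imiquimod and higher with LPS numbered 101. Independent lists would share 417.8 and 375.6 such genes, so opposite calls were fewer than independence gives. In the 100 simulations of unchanged groups, at most 4 genes were called in all for imiquimod and at most 3 for LPS, and opposite calls were not counted apart. The 101 include 7 of 45 interferon-stimulated genes and 3 of 14 MHC class II genes. Chosen after their values were seen, Ifit1bl1 stood at -0.59 with imiquimod and 3.80 with LPS on the log2 scale, Ly6a at -0.46 and 1.57, and Cd74, the invariant chain of MHC class II, at -0.46 and 1.09. The 49 include 4 of 34 ribosomal protein genes, 2 of 20 genes of the unfolded protein response, 1 of 13 mitochondrially encoded genes and Mt2, a metallothionein gene (0.64 and -0.71).

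Mitochondrially encoded transcripts were lower with LPS than with imiquimod. Of the 13 genes, 7 have near-identical nuclear copies, 7 in all, to which they could have lost reads. After the counts of the copies were added, all 13 genes were higher with imiquimod, with a median log2 difference of 1.12 (0.58 to 1.35), so a division of reads among these copies does not account for the pattern. The genes with their copies took 1.33% to 1.46% of the counts with DMSO, 1.52% to 1.58% with imiquimod and 0.855% to 0.893% with LPS. Differences in poly(A) selection or RNA handling between the groups were not tested, since the labels give no batches or dates, and neither was a loss of mitochondrial transcripts in cells treated with LPS.

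Ribosomal protein transcripts showed the same direction, with a median log2 difference of 0.43, although the list was not called with an estimated correlation of 0.87 between its genes (adjusted p = 0.324). Adding 113 near-identical copies to 33 of the 34 members gave 0.42, which argues against reads shared with pseudogenes. Genes outside the lists matched in exon length and expression had a median of 0.04, and 1000 draws ran from -0.14 to 0.16. Matched in coding length they had a median of 0.03 (-0.06 to 0.15). The list lay above every draw, but the highest draws passed 0.11, the bound set for excluding length, so a part of the pattern could still come from short transcripts.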

How the results depend on the processing

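The counts of genes called stayed within 1.5 times their values under most alternatives. These were other scalings, DESeq2, voom, a filter of 1 CPM in 3 libraries, fits to the compared groups alone and each library left out. Fits to the compared groups alone called 4002 genes for imiquimod against DMSO (4496 in the main fit). They called 5816 for LPS against DMSO (4772) and 3037 for imiquimod against LPS (3660). Calls thus fell in the comparisons with imiquimod, whose libraries differed most from each other, and rose in the one without it. Counts of lists and of shared genes also stayed within 1.5 times under these settings where they were computed. Lists were not tested with DESeq2 or voom, and shared genes were not counted in fits to the compared groups alone. The exceptions follow. A fold minimum of 1.5 left 832 genes for imiquimod against DMSO, 1012 for LPS against DMSO and 328 for imiquimod against LPS, since it tests for a larger change. With an estimated correlation between genes, 5, 5 and 4 lists were called in that order. In camera that setting also takes the degrees of freedom from the libraries, where the preset takes them from the number of genes. The settings thus differ in more than the correlation, and what each difference did was not tested apart. Lists with estimates below the preset 0.01 lost calls too, so a higher correlation among a list's own genes does not account for those losses. Osteoclast markers with imiquimod (estimate -0.054) went from a camera adjusted p of 0.0032 to 0.0879. Cholesterol synthesis with LPS (0.0068) went from 0.0112 to 0.0911. Mitosis (0.0094) and alternative activation (-0.031) with imiquimod kept their calls. Called with fry, which takes no account of genes outside a list, imiquimod against LPS had 28 lists. The correlation of fold changes was held to another bound, its standard error from leaving out each library in turn. It was not computed in fits to the compared groups alone or with the fold minimum. It stayed within that bound except without a low-count filter, where it was 0.531 against 0.708, with 25857 genes tested. Leaving out 1 library gave 3683 to 4963, 3945 to 4143 and 2653 to 4310 genes, 16 to 18, 22 to 24 and 16 to 18 lists, a correlation of 0.663 to 0.728 and 2277 to 3164 shared genes. With the replicate number as a replicate block, the counts were 4449, 4683 and 3561 genes and 16, 24 and 18 lists. Libraries of the same number were not more alike (r -0.089 to 0.082) than those of different numbers (-0.1 to 0.086). So few libraries cannot exclude that a shared number marks pairs, and the labels do not say what it means. No called gene or list turned direction with a call in these alternatives. Genes with few counts, such as Il6 and Il12b, are limited by depth.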

Other observations

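The test for T-cell transcripts was chosen after the result was seen, as were the genes named in the next paragraphs.

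Of genes known for roles in iron handling, the 5 given here were picked by their values, and no list of such genes was tested. Slc40a1, the iron exporter ferroportin, fell from 86.4 ± 2.64 CPM with DMSO to 23 ± 1.91 with imiquimod (log2 fold change -1.90 ± 0.06, adjusted p = 2.96e-12) and 19.4 ± 0.686 with LPS (-2.15 ± 0.07). Tfrc, the transferrin receptor, fell from 337 ± 5.12 to 209 ± 18.4 and 122 ± 8.94 CPM. Lcn2, which encodes a protein that binds bacterial iron carriers, rose from 18.4 ± 0.38 to 133 ± 12.4 and 122 ± 3.51 CPM. Hmox1, a haem oxygenase, rose from 1090 ± 55 to 2050 ± 101 with imiquimod and 1590 ± 45.7 CPM with LPS, and Cp, ceruloplasmin, from 8.65 ± 0.379 to 44.8 ± 3.3 and 27.2 ± 1.63 CPM. Hmox1 and Cp were higher with imiquimod than with LPS (0.37 ± 0.05 and 0.72 ± 0.07).

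Receptor genes and an acute-phase gene also changed. Fpr1, a formyl peptide receptor, rose from 20 ± 1.71 CPM to 318 ± 22.2 with imiquimod and 300 ± 11.2 with LPS. Ptafr, the receptor for platelet-activating factor, fell with imiquimod from 316 ± 8.05 to 164 ± 12.8 CPM (-0.95 ± 0.06, adjusted p = 3.34e-09) and was not called with LPS (-0.04 ± 0.06, adjusted p = 0.62). Saa3, an acute-phase gene, rose from 1260 ± 17.7 to 8440 ± 1040 with imiquimod and 5210 ± 269 CPM with LPS.

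A hypothesis was tested that imiquimod gives a uniformly weaker form of the LPS response, so that interferon-stimulated genes lag no more than others. For the 45 interferon-stimulated genes the median ratio of the imiquimod to the LPS log2 fold change was 0.14. Genes outside the list with like LPS changes had a median ratio of 0.58, and 1000 draws ran from 0.33 to 0.89. The 22 classical activation markers raised by LPS had 0.85. The values argue against a uniformly weaker response, while dose, uptake and a different time course of the interferon arm stay open, as 1 dose and 1 time were measured.

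Cd28 and T-cell receptor segments in the DMSO libraries raised the question of T cells among the cultured cells. Lck was the highest of Cd3e, Cd3d, Cd3g, Trac and Lck, at 2.19% of the Cd28 level in a DMSO library, far below what T cells would bring. Cd3e reached at most 0.123 CPM, where Cd28 lay between 45.2 and 54.1 CPM.

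Each comparison was repeated for all 10 splits of its 6 libraries into 3 and 3, and in each case 1 split, the real one, gave as many calls. Genes called and the highest of the other splits were 4496 and 0 for imiquimod against DMSO, 4772 and 1 for LPS against DMSO, and 3660 and 1 for imiquimod against LPS. For lists they were 16 and 13, 24 and 18, and 18 and 14. Every other split mixes libraries of both groups on each side, which widens the spread within a side and keeps part of the real difference. Those counts are therefore not what unchanged groups would give. With 10 splits, no share under 0.05 can be reached.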
